A study of Mus musculus with 4 samples.

How the data were processed

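Single bone marrow cells of C57BL/6 mice were measured on 4 plates of 384 wells. Per the labels' protocols, marrow was dissociated with collagenase IV (2 mg/mL) and dispase (1 mg/mL), single cells were sorted into mineral oil and lysed at 65 °C for 5 min, and libraries made by SORT-seq were read on an Illumina NextSeq500 with 75 bp paired ends. SORT-seq is a plate method that tags each well with a cell barcode and each transcript with a unique molecular identifier (UMI). The cells were CD51-negative cells that the labels call TNCs, an abbreviation the labels do not spell out, sorted as CD44+ or CD44-. One plate held the CD44+ sort and another the CD44- sort, both from the same flow cell. Each of the other 2 plates held the CD44+ sort in rows A to H and the CD44- sort in rows I to P, both from the other flow cell.

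The deposited values are expected counts, that is, transcripts per gene and well estimated by the authors from UMIs, with no scaling between wells. Per the submitters' processing notes, BWA 0.7.15 and genome build mm10 were used; the counter, the annotation and the use of strand are not given in the sources used here. Low values are whole, and higher ones follow the curve of a correction for UMI saturation with 4096 possible UMIs: of 821564 values above 0, 99.98% returned to a whole number within a tolerance of 0.011 when that correction was undone. The correction added 2.30% to the summed transcripts. No label records this step, so it is inferred from the values; plain counts had been assumed before the data were examined, and the values were rounded to whole numbers after summing, as the test needs. The tables held 17507 gene names and 79 spike-in names, and 0 names that stand for no gene.

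Wells are numbered 1 to 384, and were read in row order over 16 rows and 24 columns, which the labels do not state. A technical check bears on this: with that order, the median spike-in count of plate columns 22 to 24 was 42.2 and 59.4 times lower than that of the other columns on the plates with both sorts, and 1.22 and 1.35 times lower on the plates with a single sort. Gene expression was not used to place wells.

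A well was kept as a cell with at least 1000 transcripts assigned to genes. This kept 343 of 1536 wells, 238 from the CD44+ sort and 105 from the CD44- sort, and left out 1193. No doublet caller was run, because the labels describe sorted single cells; leaving out wells above the 99th percentile of their plate was an alternative. A well was called low in quality where Kcnq1ot1 and the transcripts that accompany it took at least 10% of its total or mitochondrial genes at least 50%; these limits were set after the data were seen and marked 112 of the 343 kept wells (32.7%), which stayed in the main comparison and were left out in an alternative.

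Transcripts of the kept wells were summed per plate and sort, giving 3 libraries per sort. Replicate 1 of each sort is its whole plate, and replicates 2 and 3 are the row blocks of the shared plates. The labels do not say which animals gave which plate, so p-values measure only the spread between these libraries, which may be technical. The libraries were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM normalization, genes kept by filterByExpr, two-sided, Benjamini-Hochberg adjusted p with a threshold of 0.05), without a covariate. The SE of a log2 difference in edgeR is its absolute value divided by the square root of the test's F statistic, not a fitted standard error. CPM values were scaled by the summed library alone, without the TMM factor. Log2 ratios of a single gene within a pair were taken after adding 10 CPM to each value; those of a list were taken from its summed CPM.

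Whether same-numbered libraries belong together was checked by correlating their deviations from the mean of their sort across genes. The correlations were 0.42, 0.29 and 0.34 for the 3 same-numbered pairs, and between -0.35 and 0.07 for the 6 other combinations. Deviations of a sort's 3 libraries sum to 0 for each gene, so positive values for same-numbered pairs push the others below 0. The gap between them is therefore in part arithmetic. The labels also put both sorts of replicates 2 and 3 on a shared plate. The numbers were therefore taken to pair the libraries, and a fit with the pair as a block is given beside results whose call or count it changes; calls of that fit had been seen before the correlations were computed.

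Gene lists were fixed before the data were examined: 14 lists of cell type markers and 14 of gene groups. The 20 lists with at least 3 tested members were compared with limma 3.58.1 (camera with a preset inter-gene correlation of 0.01 on log CPM, camera with an estimated correlation, and fry), adjusted over the 20 lists. The 8 lists with fewer tested members were those of megakaryocytes, T, NK and innate lymphoid cells, mast cells and basophils, eosinophils, endothelial cells, Schwann and neural cells, replication-dependent histones, and the genes of the sorting antigens. Where the tables use an older symbol it was matched, and list members without a value were not analysed here.

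Kept wells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15: totals scaled to 10000, log values, 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 1. A cluster was named after a marker list when at least 3 of the list's genes were among its 50 leading genes by fold, no other list had as many, and its 10 leading genes held no more markers of another list than of its own. The markers were fixed beforehand and this naming rule was written after the data were seen. Shares of classes, of cells with a transcript of a sorting antigen's gene, and median transcripts per cell were compared between the sorts by an exact two-sided permutation test over 3 against 3 libraries, whose smallest possible p is 0.1. Shares of single libraries carry exact Clopper-Pearson 95% intervals, which cover counting error only; a count of 0 allows up to 3 counts of the total. For shares of cells with a transcript, each cell was thinned to 1000 UMIs, which left out 1 CD44- cell and 0 CD44+ cells. A comparison of genes within a class had been planned for classes with at least 10 cells in 2 libraries of each sort; no class met this, so it was not run.

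Genes named in the text were chosen by a rule fixed before the data were examined: among genes past the threshold with at least 50 CPM in the higher sort and 1 direction in all 3 pairs, the 12 with the largest fold change each way, the 4 genes of the sorting antigens, and up to 4 members of a described list with the smallest p. The same rule was applied to the blocked fit. Ribosomal, mitochondrial and predicted genes are given only as counts. Not every gene this rule allows is named, and 1 result it selects is not reported here.

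Alternatives fixed beforehand were DESeq2 1.42.0, no TMM, no gene filter, other limits on transcripts per well, whole UMIs, cells thinned to 1000 UMIs, the pair or the flow cell as a covariate, each library left out in turn, only the shared plates, other tests of lists, and other clustering settings. Added after the data were seen were the comparisons without wells of low quality, without stromal-like wells and with the block combined with another setting. Camera on lists with every cell and sum thinned, and clustering without mitochondrial or called genes, were added then too. Depth set the precision: summed libraries held 97042 to 1707320 transcripts. On simulated counts for 2053 genes with the depths of these libraries, the unblocked comparison recovered 3, 27, 45 and 48 of 50 genes changed 2-, 4-, 8- and 16-fold, with 9 false calls among 132. The blocked comparison recovered 2, 25, 43 and 48 of 50, with 7 false calls among 125. In the test of camera, a simulated list of 20 genes raised 2-fold had an adjusted p of 3.45e-08, and 0 of 20 unchanged lists were called. In the real data the estimated inter-gene correlation ranged from 0.04 (p53 targets) to 0.80 (neutrophil lineage), with 0.72 for the stromal list. These lie above the preset 0.01, so the simulated lists do not show how often camera calls lists of such correlation by error.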

Results

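Single bone marrow cells that lack CD51, the integrin alpha V chain encoded by Itgav, were compared between a sort that carried the hyaluronan receptor CD44 and a sort that did not. The series asks about the hematopoietic origin of marrow cells without CD45, so the transcripts of interest are those of blood lineages and of the marrow stroma. Transcript counts were analysed for 343 cells on 4 plates, which form 3 libraries per sort. Replicate 1 of each sort is a whole plate (pair 1, 1 flow cell), and replicates 2 and 3 are row blocks of plates that held both sorts (pairs 2 and 3, the other flow cell). The CD44+ libraries held 56, 95 and 87 cells with medians of 1994, 5162 and 11225 transcripts per cell, and sums of 149707, 1118720 and 1707320 transcripts. The CD44- libraries held 44, 24 and 37 cells with medians of 1848, 1795 and 2544 transcripts per cell, and sums of 97042, 101367 and 158763 transcripts. Wells of low quality made up 53.6%, 41.1% and 23.0% of the CD44+ cells and 40.9%, 4.17% and 10.8% of the CD44- cells in replicates 1, 2 and 3.

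Cd44 transcripts did not separate the sorts. The gene, at chromosome 2 from 102811141 to 102901665 on the reverse strand of GRCm38 (mm10; GENCODE vM21), stood at 201 ± 97.3 CPM in the CD44+ sort and 194 ± 131 CPM in the CD44- sort (SD, n = 3 libraries each), a log2 difference of -0.04 (SE 0.50, adjusted p = 0.973 in edgeR). Its level therefore gave no check of the sort labels. Ptprc, which encodes CD45, stood at 108 ± 61.0 CPM in the CD44+ sort and 260 ± 144 CPM in the CD44- sort, a log2 difference of -1.37 (SE 0.73, adjusted p = 0.341). With the pair as a block Ptprc was lower in the CD44+ sort (adjusted p = 0.0412), with log2 ratios of -1.18, -1.23 and -1.14 on the 3 pairs. These levels are shares of a library's total, and CD44+ cells of pairs 2 and 3 held more transcripts. In counts, Ptprc had 21 transcripts in 56 CD44+ cells against 32 in 44 CD44- cells on pair 1. On pair 2 it had 163 in 95 against 36 in 24, and on pair 3 64 in 87 against 15 in 37. Per cell it was thus lower in the CD44+ sort on pair 1 only. Itgav and Pecam1, which encodes the endothelial antigen CD31, were below the gene filter.

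After thinning to 1000 UMIs, a Cd44 transcript was found in 12.9% ± 5.43 of CD44+ cells and 12.1% ± 8.57 of CD44- cells (SD, n = 3; exact permutation p = 0.9). Ptprc was found in 9.04% ± 5.65 against 15.3% ± 6.43 (exact p = 0.3), with 8.93%, 14.7% and 3.45% against 20.5%, 17.4% and 8.11% in replicates 1, 2 and 3. Itgav was found in 1.08% ± 1.05 against 4.77% ± 0.56 (exact p = 0.1) and Pecam1 in 3.22% ± 3.77 against 1.52% ± 2.62 (exact p = 0.7). Adjusted over the 4 genes, these exact p-values were 0.9, 0.6, 0.4 and 0.9. Without thinning the means were 46.6% against 27.2% for Cd44, 29.5% against 29.4% for Ptprc, 5.64% against 13.3% for Itgav and 8.79% against 4.56% for Pecam1. By class, Ptprc was found in 8 of 20 neutrophil lineage-like cells and 12 of 51 B progenitor-like cells, but in 1 of 35 late erythroid-like cells and 0 of 17 stromal-like cells, which at this depth allows up to 17.6% of such cells with a Ptprc UMI and sets no limit on cells that express the gene. Median depths of these classes before thinning were 3368, 4219, 12480 and 6572 transcripts. Pecam1 was found in 1 of 35 late erythroid-like cells (2.86%), a level like its shares in both sorts, and in 7 of 51 B progenitor-like cells.

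Genes of the marrow stroma were lower in the CD44+ sort. Of 2463 genes tested, 24 were lower in the CD44+ sort, by 8.49- to 35.1-fold, and they included Kitl, which encodes stem cell factor (log2 difference -4.11, SE 0.69, adjusted p = 0.0410), and Sparc, which encodes the bone matrix protein osteonectin (-4.08, SE 0.68, adjusted p = 0.0410). Others encode the mesenchymal cell surface protein Islr (-5.13, SE 0.67, adjusted p = 0.0268), the lectin receptor Cd302 (-4.94, SE 0.63, adjusted p = 0.0268) and the adhesion proteins Vcam1 (-4.41, SE 0.71, adjusted p = 0.0410) and Cdh11 (-4.32, SE 0.64, adjusted p = 0.0358). The secreted or matrix proteins Igfbp7, Fbln5, Ogn and Gas6, the kinase Mylk and the receptor Antxr1 differed by -4.46 to -4.12. In CPM, Kitl stood at 32.4 ± 19.7 against 571 ± 388, Sparc at 58.8 ± 28.8 against 985 ± 846 and Vcam1 at 17.5 ± 10.5 against 389 ± 378 (SD, n = 3).

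Only 1 gene was higher in the CD44+ sort in the same test. Alad, which encodes an early enzyme of heme synthesis and lies on chromosome 4 from 62509169 to 62519918 on the reverse strand, stood at 232 ± 96.7 against 32.5 ± 20.1 CPM (SD, n = 3, log2 difference 2.72, SE 0.49, adjusted p = 0.0488 in edgeR). In CD44- replicates 1, 2 and 3 it stood at 10.3, 49.3 and 37.8 CPM. With sums of 97042, 101367 and 158763 transcripts, these are few transcripts, near the floor. All 25 genes had the same direction in the 3 pairs, and 470 genes had an unadjusted p under 0.05. With the pair as a block, 43 genes were higher and 113 lower in the CD44+ sort, including all 25. The genes higher with the block included the erythroid carbonic anhydrase gene Car1 (log2 difference 2.55, SE 0.46, adjusted p = 0.0104) and Add2, which encodes a protein of the red cell membrane skeleton (2.38, SE 0.55, adjusted p = 0.0318). They also included the asparagine synthetase gene Asns (2.94), the amino acid transporter gene Slc38a5 (2.27), the sphingosine kinase gene Sphk1 (2.19) and the kinetochore gene Cenph (2.43). Asns, Cenph and Add2 had means of only 14.4, 16.5 and 22.6 CPM in the CD44- sort, again few transcripts. Cxcl12, the chemokine gene of marrow stroma on chromosome 6 from 117168535 to 117181367, was lower with the block (-4.93, SE 0.51, adjusted p = 0.000824), at 431 ± 352 against 10387 ± 8517 CPM. Cxcl14 (-5.53), Fstl1 (-4.79), Epas1 (-4.48), Igfbp5 (-4.45) and Cyp1b1 (-4.35) were lower with it too. DESeq2 on the same libraries called 98 genes higher and 172 lower. On the shared plates alone, 1 gene was higher and 160 lower, and pair 1 has a single library per sort and no test of its own; 0 genes passed an edgeR test of whether the sort difference depended on the flow cell, with 87 at an unadjusted p under 0.05.

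These counts rest on few libraries and wells. Leaving out CD44+ replicate 1, 2 or 3 or CD44- replicate 2 or 3 left 0 and 0 genes in edgeR, with 336 to 619 at an unadjusted p under 0.05, whereas without CD44- replicate 1 the counts were 7 and 108; thinning every cell to 1000 UMIs reduced the genes tested to 505 and the calls to 0 and 0, with 42 at an unadjusted p under 0.05. Without the 17 stromal-like wells 0 and 0 of 1778 genes passed in edgeR, with 231 at an unadjusted p under 0.05, and 0 and 1 (Cxcl12) with the block, while Alad stood at 2.34 in both fits.

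**Figure D1:**
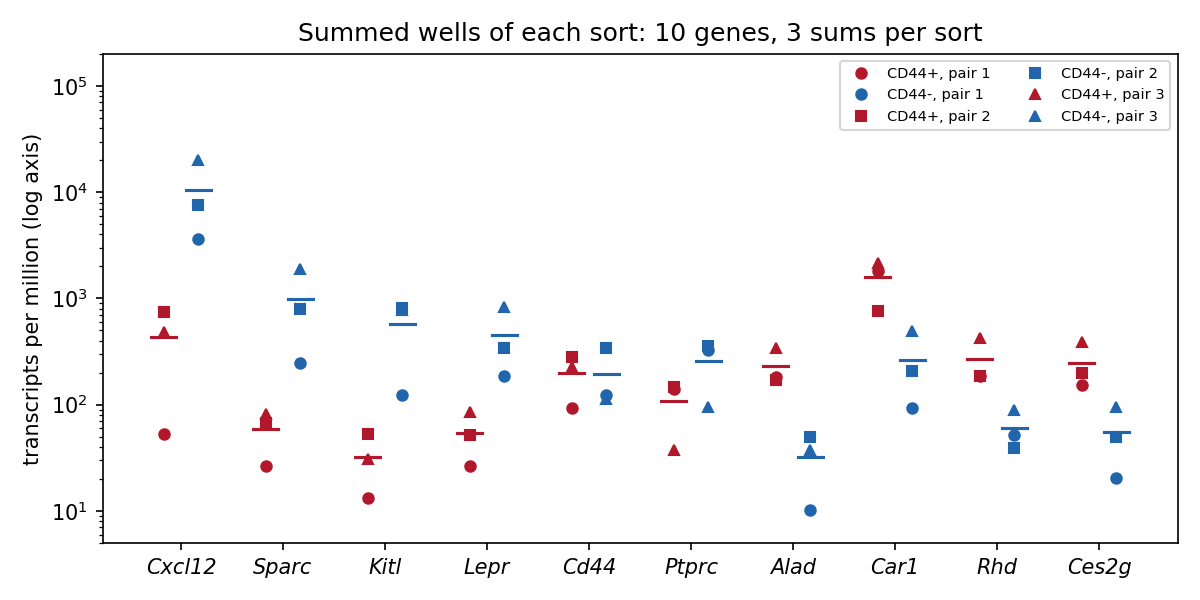
Level of 10 genes in the 6 summed libraries, on a log axis of CPM. Points are libraries, with the marker giving the pair, and bars are the mean of the 3 libraries of a sort. Kitl, Sparc, Lepr and Cxcl12 lie lower in the CD44+ libraries of all pairs, Alad, Car1, Rhd and Ces2g lie higher, and Cd44 overlaps between the sorts.

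The list of mesenchymal stromal and bone genes was lower as a whole. All 14 tested members had a fitted log2 difference below 0, with a median of -3.65. Runx2, a transcription factor of bone formation (-3.77, SE 0.62), Sparc, Kitl and the leptin receptor gene Lepr (-3.09, SE 0.55) were lower over all genes tested in edgeR, all 14 were lower when adjusted over the list alone, and 13 were lower over all genes with the pair as a block. The list's summed level was 261, 2039 and 1231 CPM in the CD44+ libraries and 7307, 14851 and 36838 CPM in the CD44- libraries of pairs 1, 2 and 3. Its adjusted p in camera was 6.13e-13 with the preset correlation; the adjusted p = 0.388 with an estimated correlation. Beside this difference, 17 wells had a stromal-like transcriptome, 4 of them among 238 CD44+ cells and 13 among 105 CD44- cells, and these wells held 77.0% and 93.3% of the 14 genes' transcripts in the 2 sorts. Without them none of the 24 lower genes passed the gene filter. The list was then lower by its 3 members that did (camera adjusted p = 0.000167 with the preset correlation). Of these, 0 passed over all genes in edgeR and 1 with the pair as a block, and an estimated correlation was not tried there. The preset 0.01 lies far below the 0.72 estimated for the whole list, so this camera p carries little weight. Transcripts of the 14 genes per remaining well were alike on the shared plates, at 6.27 (CD44+) against 8.35 (CD44-) on pair 2 and 4.24 against 4.22 on pair 3. Those 2 pairs therefore do not show that a difference remained.

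Erythroid progenitor genes were higher in the CD44+ sort as a list. Of its 20 tested members 19 had a fitted log2 difference above 0, with a median of 1.59. Over all genes tested 0 members passed in edgeR without the block; 12 were higher and 1 lower when adjusted over the list alone, and 8 were higher and 1 lower over all genes with the pair as a block. Those higher with the block included Car1, the Rh blood group gene Rhd (2.05, SE 0.39, adjusted p = 0.0141) and the carboxylesterase gene Ces2g (2.09, SE 0.42, adjusted p = 0.0195). The lower member was the apolipoprotein gene Apoe (-3.39, SE 0.71, adjusted p = 0.0232 with the block), which is also expressed by macrophages and stromal cells. The summed level of the list was 8137, 5533 and 12332 CPM in the CD44+ libraries and 2515, 2605 and 4977 CPM in the CD44- libraries of pairs 1, 2 and 3. Its adjusted p in camera was 8.01e-08; the adjusted p = 0.388 with an estimated correlation.

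Genes of heme synthesis were higher as a list, with 9 of 12 tested members above 0 and a median log2 difference of 0.96. The list's summed level had log2 ratios of 0.08, 0.63 and 1.19 on the 3 pairs, so it hardly differed on pair 1. Alad was higher over all genes tested, 4 members were higher and 1 lower when adjusted over the list alone, and 3 were higher with the pair as a block, namely Alad, Tmem14c (1.56, SE 0.35, adjusted p = 0.0281), which moves a heme precursor into mitochondria, and Cpox (1.92, SE 0.33, adjusted p = 0.00861), an enzyme of the pathway. Alas2, the first enzyme of the pathway in red cells, stood at 63.4 ± 20.9 against 274 ± 281 CPM (log2 difference -2.28, SE 0.76, adjusted p = 0.172). The list's adjusted p in camera was 0.0244; the adjusted p = 0.557 with an estimated correlation. Its adjusted p was 0.0755 without wells of low quality and 0.292 without stromal-like wells, with medians of 1.02 and 0.96 over 11 and 9 tested members.

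Late erythroid genes did not pass as a list (camera adjusted p = 0.348, median log2 difference -0.75 over 14 members). With 1 library left out the median went from -1.31 (without CD44+ replicate 3) to -0.10 (without CD44- replicate 1). Over all genes 0 members passed in edgeR, and 1 was lower when adjusted over the list alone. With the pair as a block Prdx2, a peroxiredoxin abundant in red cells, was higher in the CD44+ sort (1.38, SE 0.29, adjusted p = 0.0235) and Tmcc2 lower (-4.08, SE 0.63, adjusted p = 0.00416). The globin gene listed as Beta-s, which has near-identical copies in the genome, stood at 33557 CPM in CD44- replicate 1 and at 1196 to 4095 CPM in the other 5 libraries. The list's log2 ratios were -3.69, 0.21 and -0.37 on the 3 pairs; its adjusted p was 0.0236 without CD44- replicate 2 and 0.0167 without stromal-like wells, lower in the CD44+ sort both times, and its median was -0.10 without CD44- replicate 1 (adjusted p = 0.843), with the sign of the test turning.

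Genes of DNA replication and of ribosomes were higher in the CD44+ sort as lists, by smaller amounts. In the S phase list 20 of 22 tested members were above 0, with a median log2 difference of 0.88. Over all genes 0 passed in edgeR with or without the block, and 5 were higher when adjusted over the list alone. The ribonucleotide reductase gene Rrm1 (1.34, SE 0.36, adjusted p = 0.117) and the helicase genes Mcm6 (1.16) and Mcm5 (1.15) were among the members with the smallest p-values. The list's adjusted p was 1.55e-05 in camera, 0.0312 in fry and, as the adjusted p with an estimated correlation, 0.388. In the list of cytosolic ribosomal proteins 71 of 72 tested members were above 0 (median 0.72), 0 passed over all genes or over the list alone and 9 were higher with the pair as a block. Its adjusted p was 3.84e-14 in camera, 0.0312 in fry and, as the adjusted p with an estimated correlation, 0.388. Genes of G2 and mitosis had 18 of 19 members above 0 (median 0.54), with Mki67 at 642 ± 169 against 349 ± 19.7 CPM (0.76, SE 0.29, adjusted p = 0.213). Their summed level had log2 ratios of -0.10, 1.05 and 1.12 on the 3 pairs, so it was not higher on pair 1. Their list's adjusted p was 0.00422 in camera and, as the adjusted p with an estimated correlation, 0.566. Without CD44- replicate 2 it was 0.0702 with a median of 0.61, and without stromal-like wells 0.203 with a median of 0.35. With 1 library left out the median went from 0.53 (without CD44+ replicate 3) to 1.00 (without CD44- replicate 1).

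Mitochondrially encoded genes were higher as a list, with 9 of 13 members above 0 and a median log2 difference of 0.28 (camera adjusted p = 0.0442; adjusted p = 0.652 with an estimated correlation). In edgeR 0 of the 13 passed over all genes or over the list alone without the block, and 1 was higher with it. The summed level of the list had log2 ratios of 1.25, -0.14 and 0.62 on the 3 pairs, so it was not higher on pair 2. The list's direction turned without the wells of low quality (adjusted p = 0.899), which include wells chosen for a high mitochondrial share. Its adjusted p was also 0.324, 0.0758 and 0.193 without CD44- replicate 1, CD44+ replicate 2 and CD44- replicate 3, with medians of 0.02, 0.29 and 0.09. The median was 1.09 without CD44- replicate 2 and 0.60 without CD44+ replicate 3.

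Pan-haematopoietic and B progenitor genes were lower in the CD44+ sort as lists, in sums where wells with more transcripts weigh more. With every cell and sum thinned, neither list had enough genes left to test. The mean share of B progenitor-like cells was 14.7% in the CD44+ sort and 12.1% in the CD44- sort (exact permutation p = 0.7). That share was lower in the CD44+ sort on pair 1 (14.3% against 22.7%) and pair 3 (5.75% against 13.5%). It was higher on pair 2 (24.2% against 0 of 24 cells), so the cell shares do not settle a direction. All 11 tested pan-haematopoietic members were below 0, with a median log2 difference of -0.92. With the pair as a block 2 of them passed over all genes, Ptprc and Cd53, a tetraspanin of blood cells (-1.59, SE 0.32, adjusted p = 0.0194); Runx1, a transcription factor of blood cells, stood at 44.3 ± 33.3 against 221 ± 191 CPM (-2.34, SE 0.66, adjusted p = 0.126). The list's adjusted p was 0.0170 in camera and, as the adjusted p with an estimated correlation, 0.571. It was 0.159, 0.0827 and 0.130 without CD44- replicate 1, CD44- replicate 2 and CD44+ replicate 3, with medians of -0.59, -0.49 and -0.38, and the median was -0.53 without CD44+ replicate 1. Of 16 tested B progenitor genes 15 were below 0 (median -0.81) and 0 passed in edgeR, the lowest p being that of Fcrla (-2.12, SE 1.04, adjusted p = 0.302). With the block Akap12 was lower (-2.26, SE 0.59, adjusted p = 0.0485). The list's adjusted p was 0.00422 in camera and, as the adjusted p with an estimated correlation, 0.626. Its log2 ratios were -1.14, 0.24 and -2.90 on the 3 pairs, and without CD44+ replicate 3 its adjusted p was 0.434 with a median of -0.21. The median was -1.92 without CD44+ replicate 2 and -0.48 without CD44- replicate 1.

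Myeloid and other blood lists did not pass. Neutrophil lineage genes had log2 ratios of -2.32, -1.56 and 2.93 on the 3 pairs (camera adjusted p = 0.971), with lactoferrin (Ltf) at 1525 and 3059 CPM in CD44- replicates 1 and 2 and 31.5 CPM in replicate 3. That list's adjusted p was 4.83e-07, lower in the CD44+ sort, without CD44- replicate 3, and its median log2 difference, -1.34, was -1.32, -1.12, -0.84 and -0.73 without CD44+ replicate 1, CD44+ replicate 3, CD44- replicate 1 and CD44- replicate 2, with the sign of the test turning in these 4. Monocyte, macrophage and dendritic genes had an adjusted p of 0.976, a median log2 difference of 0.13 and a mean of -0.13, the sign of the test being that of the mean. Adjusted p-values in camera were 0.695 for stem and multipotent progenitor genes, 0.190 for mature B and plasma cell genes, 0.695 for iron handling, 0.121 each for immediate early and heat shock genes, p53 targets and cytokine receptors, 0.0999 for the pre-B cell receptor and 0.0584 for adhesion genes. With the pair as a block 3 of these passed in camera as lower in the CD44+ sort, the immediate early and heat shock genes (0.0148), the pre-B cell receptor genes (0.0409) and the adhesion genes (0.0324), and their adjusted p-values with an estimated correlation were 0.564, 0.636 and 0.465. Jun (-2.53, SE 0.62, adjusted p = 0.0398) and Fosb (-2.78, SE 0.65, adjusted p = 0.0386) were the 2 immediate early genes lower with the block. Vcam1 was the 1 adhesion gene lower over all genes. With 1 library left out, some of these lists passed as lower in the CD44+ sort: the immediate early and heat shock genes without CD44+ replicate 1 (0.000640) or CD44- replicate 2 (0.000362), and the pre-B cell receptor genes without CD44+ replicate 1 (0.0467) or 2 (0.00846). The pre-B cell receptor and adhesion lists also passed with at least 2000 transcripts per well (0.0417 and 0.0361) and without stromal-like wells (0.00167 and 0.00969). The cytokine receptors passed without CD44+ replicate 2 (0.0116) and the adhesion genes without CD44- replicate 3 (0.00285).

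Of 343 cells, 166 fell in 6 of 11 clusters that could be named. Of these 149 were like cells of a blood lineage and 17 were stromal-like, and 0 clusters were named endothelial or Schwann cells. Erythroid progenitor-like cells made up 21.4%, 5.26% and 26.4% of the CD44+ cells and 2.27%, 0% and 5.41% of the CD44- cells in replicates 1, 2 and 3, with 0 of 24 cells allowing a share of up to 12.5%. The means were 17.7% ± 11.1 and 2.56% ± 2.71 (SD, n = 3; exact permutation p = 0.2; 40 of 238 and 3 of 105 cells), higher in the CD44+ sort in 3 of 3 pairs. Stromal-like cells made up 1.44% ± 1.60 and 11.9% ± 13.1 (exact permutation p = 0.1, the smallest possible), lower in the CD44+ sort in 3 of 3 pairs. They were 0 of 56, 3 of 95 and 1 of 87 CD44+ cells and 2 of 44, 1 of 24 and 10 of 37 CD44- cells in replicates 1, 2 and 3. Pairs 1 and 2 thus rest on 2 and 1 CD44- wells, and 10 of the 13 in the CD44- sort lay in replicate 3. Without that library the difference was -2.92 percentage points in place of -10.5. An exact test that flips the signs of the within-pair differences gave p = 0.25 for stromal-like and for erythroid progenitor-like shares. That is the smallest p that 3 pairs allow. Late erythroid-like cells made up 9.28% against 9.54% (exact p = 1), B progenitor-like cells 14.7% against 12.1% (exact p = 0.7) and neutrophil lineage-like cells 4.30% against 8.08% (exact p = 0.6). Adjusted over the 5 classes the p-values ranged from 0.5 to 1. Clustering without the 156 genes called in either fit gave the same 17 stromal-like wells, and 46 erythroid progenitor-like wells of which 41 were shared with the 43 above. The 156 genes were left out of the grouping only, and clusters were still named with all genes. Genes not called stayed in the grouping even where they vary with called ones. The result therefore does not show that the classes are independent of the called genes.

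The 5 unnamed clusters held the other 177 cells. Mitochondrial genes led 1 cluster of 40 CD44+ and 0 CD44- cells, with a median mitochondrial share of 77.0%, and 32 of its cells lay in replicate 2. Kcnq1ot1 and similar transcripts led a cluster of 38 CD44+ and 19 CD44- cells. A cluster with few markers held 18 of the 24 cells of CD44- replicate 2, and another, led by Ect2 and Rrm2 beside mitochondrial genes, held 23 CD44+ and 12 CD44- cells. The last was led by Mpo, Prtn3 and Ly6c2, markers of both the neutrophil and the monocyte list, with 17 CD44+ and 4 CD44- cells.

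**Figure D2:**
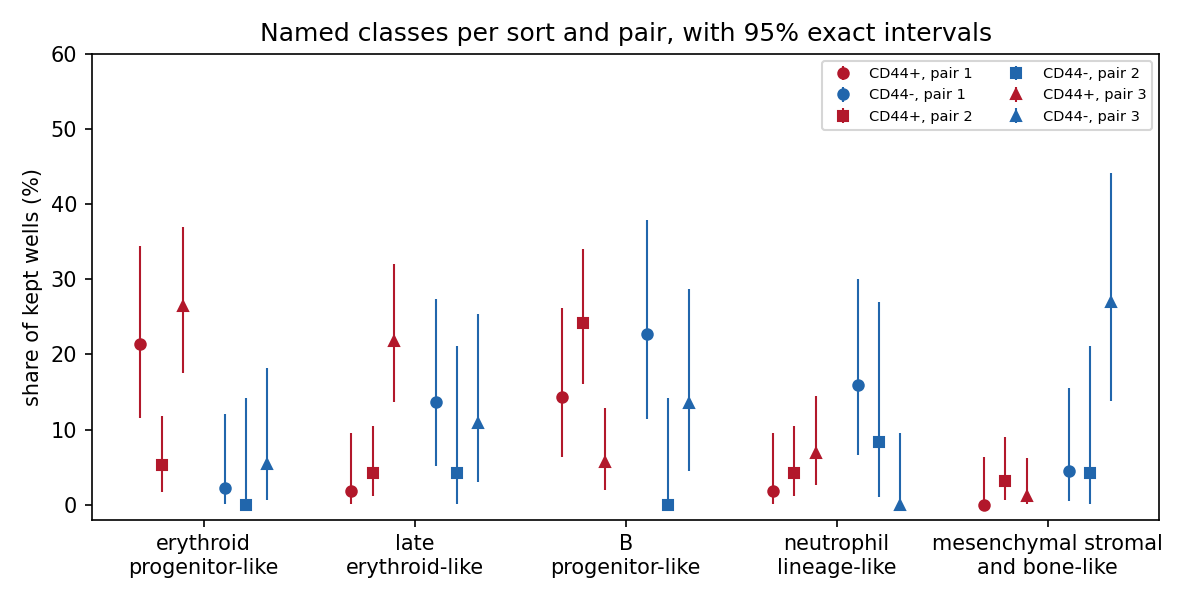
Share of kept cells in each of 5 named classes, in percent, for the 3 libraries of each sort. Points are libraries and lines are exact 95% Clopper-Pearson intervals, which cover counting error only; erythroid progenitor-like shares lie higher and stromal-like shares lower in the CD44+ library of every pair.

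CD44+ cells held more transcripts than CD44- cells in 3 of 3 pairs. The medians per library averaged 6127 ± 4690 and 2062 ± 418 transcripts (SD, n = 3), a ratio of 2.97, with an exact permutation p = 0.2. The ratio of the CD44- to the CD44+ median was 0.927 on the whole plates and 0.348 and 0.227 on the shared plates. For spike-in transcripts the same ratios were 1.17, 1.21 and 0.842. Per spike-in transcript, the medians averaged 11.3 ± 6.38 and 5.05 ± 3.86, a ratio of 2.23 (exact permutation p = 0.2). Without CD44+ replicate 3 the log2 ratio of the unscaled medians was 0.80 in place of 1.57.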

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

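The tests of free stromal RNA, of wells of low quality and of spike-in transcripts were chosen after the results they bear on were seen, as were the choice to run the stromal tests on all 14 genes without a gene filter, the condition set on their quartiles, and the table of left-out wells; the other tests were written down first. Libraries were not tested for outliers, since each sort has 3.

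In the wells left out for having too few transcripts, which no comparison above uses, the mesenchymal stromal and bone list had a mean level of 5067 ± 2588 CPM in the CD44- sort and 3243 ± 2271 CPM in the CD44+ sort (SD, n = 3; exact permutation p = 0.5). These are 762 and 219 list transcripts in all. The log2 ratio of CD44+ to CD44- wells was -3.21 on the whole plates and 0.33 and 0.24 on the shared plates.

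The lower level of stromal genes in the CD44+ sort was weighed against technical accounts, with the median log2 difference of the 14 genes at -3.15 when no gene filter was used. Without the 17 stromal-like wells the median was -2.39 (quartiles -3.00 and -1.14). The summed levels then differed by -3.33, -2.08 and -2.62 on the 3 pairs. Those wells hold most of the transcripts, and only 4 of the 14 genes were called without them, against 14 with them. These levels are shares of a library's total, and kept CD44+ wells of the shared plates held more transcripts in all. List transcripts per remaining well were alike there, so pairs 2 and 3 cannot tell whether a stromal difference remained. On the whole plates of pair 1, which held 1 sort each, 35 list transcripts remained in 56 CD44+ wells and 218 in 42 CD44- wells. For that pair the stromal-like wells are thus not the whole of the difference. Its sorts lay on separate plates, so the rest cannot be told apart from a difference between plates. Left-out wells of these plates held 61 transcripts of the whole list in 328 CD44+ wells and 480 in 340 CD44- wells. With cells and sums thinned to equal depth the median was -2.17 (quartiles -2.72 and -1.26) with 2 of the 14 genes called, and without wells of low quality -3.43 (quartiles -3.79 and -3.35), so that neither unequal depth nor low quality alone accounts for the size of the difference. Free stromal RNA in like amounts in the kept wells of a plate may account for the part outside the stromal-like wells on the shared plates. List transcripts per kept well differed there between the sorts by a ratio of 1.33 at most (CD44- over CD44+, 8.35 against 6.27 and 4.22 against 4.24). On the whole plates the ratio was 8.30. Left-out wells of pair 2 held 86.0 transcripts of the whole list in 97 CD44+ wells and 120 in 168 CD44- wells. Those of pair 3 held 72.1 in 105 and 162 in 155. These are fewer per well than in kept wells, which argues against like amounts in all wells. Left-out wells were, however, chosen for few transcripts. A difference in which stromal cells carry CD44 remains open.

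Whether chance could give the gene counts cannot be settled with these libraries. The sorts gave 25 calls, as many as in 1 of the 10 ways to split the 6 libraries, and the highest count of another split was 0; with the pair as a block they gave 156, as many as in 1 of the 4 splits that part all pairs, and the highest other was 0. Both designs have too few splits for a share under 0.05.

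The lower number of transcripts per CD44- cell on the shared plates was weighed against capture and cell mix. Spike-in transcripts, added to every well, had a CD44- to CD44+ ratio of at least 0.842 on both plates, which argues against lower capture or sequencing of those wells as the cause. Within erythroid-like wells of these plates the ratio of median transcripts was 0.0801 (2098 in 7 CD44- wells, quartiles 1317 and 4854; 26196 in 51 CD44+ wells, quartiles 13798 and 43319), which argues, on few wells, against a different mix of these classes as the whole cause. By class the ratio was 0.0632 for late erythroid-like wells (5 CD44- against 23 CD44+) and 0.272 for erythroid progenitor-like wells (2 against 28), so that few CD44- wells carry this test. Smaller or more mature cells in the CD44- sort remain open as untested hypotheses.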

How the results depend on the processing

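The comparisons without wells of low quality, without stromal-like wells, without a pair and of the block combined with another setting were chosen after the data were seen. So were camera on lists with every cell and sum thinned, and clustering without mitochondrial or called genes. The others were fixed before. The planned comparisons of genes within a class were not run, since no class had enough cells in both sorts.

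The higher number of transcripts per CD44+ cell kept its direction in all 9 alternatives, with a log2 ratio of 0.80 without CD44+ replicate 3 to 2.19 with at least 500 transcripts per well. The lower share of stromal-like cells and the higher share of erythroid progenitor-like cells in the CD44+ sort each kept their direction in all 17. These include the mean of within-pair differences, which equals the main difference by arithmetic and could not turn. No alternative clustered the cells at equal depth. The difference in the share of erythroid progenitor-like wells, 15.2 percentage points, was 30.6 when wells of low quality were left out and the rest clustered again, and 26.5 when they were left out of the denominator. The difference in the share of mesenchymal stromal and bone-like wells, -10.5 points, was -17.1 with at least 2000 transcripts, -6.93 with at least 500 and -2.92 without CD44- replicate 3. The lists of erythroid progenitor, stromal, S phase and ribosomal genes kept their direction and their call in camera with the preset correlation in every alternative in which they could be tested; with every cell and sum thinned, too few erythroid progenitor and S phase genes were left to test.

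Counts of genes moved with the processing. Genes higher and lower in the CD44+ sort were 1 and 24, against 98 and 172 with DESeq2, 0 and 21 with the total library size only, 142 and 334 with no gene filter, 1 and 40 with at least 500 transcripts, 1 and 29 with at least 2000 transcripts, and 1 and 19 with no cell filter. They were 0 and 26 without wells above the 99th percentile, 4 and 32 with whole unique UMIs, 3 and 48 with the flow cell as a covariate, 1 and 160 on only the plates with both sorts, and 6 and 50 without wells of low quality. Without stromal-like wells they were 0 and 0 among 1778 genes tested in edgeR, with 231 at an unadjusted p under 0.05, and 0 and 1 with the block. With each cell thinned to 1000 UMIs they were 0 and 0 among 505 genes tested, so that depth limits this test. With the replicate block they were 43 and 113, and with the block and another setting 32 and 97 without wells of low quality, 0 and 0 with each cell thinned to 1000 UMIs, 22 and 130 with DESeq2, 21 and 209 without pair 1, 125 and 248 without pair 2, and 16 and 77 without pair 3. Leaving out 1 library gave from 0 and 0 (without CD44+ replicate 1, 2 or 3 or CD44- replicate 2 or 3) to 7 and 108 (without CD44- replicate 1). Apart from the settings with fewer libraries or fewer transcripts, the cause was not tested.

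No list passed in camera with an estimated correlation. The adjusted p was then 0.388 for erythroid progenitor, stromal, S phase and ribosomal genes, 0.626 for B progenitor, 0.571 for pan-haematopoietic, 0.557 for heme biosynthesis, 0.566 for G2 and mitosis and 0.652 for mitochondrially encoded genes. With the replicate block and an estimated correlation it was 0.428 for erythroid progenitor, stromal, heme biosynthesis, S phase and ribosomal genes, 0.585 for B progenitor, 0.465 for pan-haematopoietic, 0.564 for G2 and mitosis and 0.636 for mitochondrially encoded genes. In fry S phase and ribosomal genes passed, and the adjusted p was 0.0577 for erythroid progenitor and for stromal genes, 0.0771 for heme biosynthesis, 0.343 for G2 and mitosis, 0.379 for pan-haematopoietic, 0.507 for B progenitor and 0.533 for mitochondrially encoded genes. With camera and fry on the main fit the median differences are those given. With the replicate block they moved, for example to -1.43 from -0.81 for B progenitor and to 0.47 from 0.28 for mitochondrially encoded genes.

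Heme biosynthesis lost its call without wells of low quality (0.0755) and without stromal-like wells (0.292), while its median log2 difference, 0.96 before, was 1.02 and 0.96 over 11 and 9 tested members in place of 12. G2 and mitosis lost its call without stromal-like wells (0.203), with a median of 0.35 in place of 0.54. The pre-B cell receptor and adhesion lists gained a call, lower in the CD44+ sort, with at least 2000 transcripts (0.0417 and 0.0361) and without stromal-like wells (0.00167 and 0.00969), and late erythroid genes without stromal-like wells (0.0167). Mitochondrially encoded genes lost it with at least 2000 transcripts (0.173) and without stromal-like wells (0.192), and turned direction without wells of low quality (0.899, median -0.43), which were partly chosen by these genes. The sign of the test turned for monocyte genes with the total library size only (0.904), in fry (0.937), with the replicate block (0.605) and with the block and an estimated correlation (0.878), and for neutrophil lineage genes with at least 2000 transcripts (0.933). The monocyte median, 0.13, was 0.24 with the total library size only and 0.52 with the block, and the neutrophil median was -1.45 in place of -1.34, so that no median changed sign in these settings. In other settings the monocyte median did: it was -0.52 with at least 2000 transcripts and -0.11 without wells of low quality. With 1 library left out it went from -0.96 (without CD44+ replicate 2) to 1.26 (without CD44- replicate 1). The cause was not tested.

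With 1 library left out, the adjusted p of the lists ranged as follows, where a turned sign is that of the test. It went from 0.0236 (without CD44- replicate 2) to 0.843, sign turned with a median of -0.10 (without CD44- replicate 1), for late erythroid genes, and from 6.29e-06 (without CD44+ replicate 2) to 0.434 (without CD44+ replicate 3) for B progenitor genes. For neutrophil lineage genes it went from 4.83e-07 (without CD44- replicate 3) to 0.939, sign turned with a median of -1.12 (without CD44+ replicate 3), and for monocyte genes from 0.0973 (without CD44- replicate 3) to 0.977, sign turned with a median of -0.11 (without CD44- replicate 2). For stem and multipotent progenitor genes the range was 0.394 (without CD44- replicate 2) to 0.976 (without CD44+ replicate 3), and for pan-haematopoietic genes 0.000206 (without CD44- replicate 3) to 0.159 (without CD44- replicate 1). For G2 and mitosis it was 3.37e-05 (without CD44- replicate 1) to 0.0702 (without CD44- replicate 2), and for mitochondrially encoded genes 6.51e-05 (without CD44- replicate 2) to 0.324 (without CD44- replicate 1). For the pre-B cell receptor and recombination list it was 0.00846 (without CD44+ replicate 2) to 0.804, sign turned with a median of 0.04 (without CD44+ replicate 3). The cause was not tested.

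Shares that did not differ by the test turned direction in places. The difference in percentage points for late erythroid-like cells was 8.22 with at least 2000 transcripts, 1.22 with wells of low quality left out of the denominator and 0.488 when clustered without mitochondrial genes, and went from -6.54 (without CD44+ replicate 3) to 3.49 (without CD44+ replicate 1). For the share of B progenitor-like wells it was -0.677 with at least 2000 transcripts, and went from -3.37 (without CD44- replicate 2) to 7.99 (without CD44- replicate 1). For the share of neutrophil lineage-like wells, -3.78 points, it was -20.6 with at least 500 transcripts and -6.85 with at least 2000, and went from -7.82 (without CD44- replicate 3) to 0.131 (without CD44- replicate 1). The share of cells with a Ptprc transcript differed by 0.0891 points when unthinned. The share of cells with a Pecam1 transcript differed by -0.691 with at least 500 transcripts, and went from -0.366 (without CD44+ replicate 2) to 3.32 (without CD44+ replicate 1), and that of Cd44 from -2.47 (without CD44- replicate 3) to 5.70 (without CD44- replicate 2). The cause was not tested.

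Of the values of named genes, 2117 kept direction and side of the threshold, 337 passed only under the alternative, 94 no longer passed and 32 reversed, none of the last being called. The Cd44 log2 fold change was 0.0383 with the total library size only, 0.41 with no gene filter, 0.0808 with at least 500 transcripts, 0.17 without wells above the 99th percentile, 0.0337 with the replicate block and 0.25 on only the plates with both sorts. With the block it was 0.0933 without wells of low quality, 0.42 without pair 1 and 0.39 without pair 2, and with 1 library left out it went from -0.36 (without CD44- replicate 3) to 0.64 (without CD44- replicate 2). Without stromal-like wells the Il1rl1 log2 fold change was -0.00808, and with the block and without these wells the Xbp1 log2 fold change was 0.12. With no gene filter Mcl1 stood at 0.0101 and Myb at 0.0524. With each cell thinned to 1000 UMIs Tfrc stood at -0.23 (-0.0234 with the block) and Vpreb3 at 0.15. On only the plates with both sorts Kit stood at -0.10 and Lyz2 at 0.46, and Kit at -0.0345 without wells of low quality. With the block Lyz2 stood at 0.80 and Ngp at 0.24 without pair 1, and Cd74 at 0.0783 without pair 3. With 1 library left out, the Cd74 log2 fold change went from -3.58 (without CD44+ replicate 1) to 0.65 (without CD44- replicate 1), that of F13a1 from -0.56 (without CD44+ replicate 2) to 1.42 (without CD44- replicate 2) and that of Kit from -0.0321 (without CD44- replicate 1) to 1.37 (without CD44- replicate 3). That of Lyz2 went from -1.38 (without CD44- replicate 3) to 0.62 (without CD44- replicate 1), that of Mcl1 from -0.78 (without CD44- replicate 2) to 0.26 (without CD44- replicate 1) and that of Slc40a1 from -0.61 (without CD44- replicate 2) to 0.0210 (without CD44- replicate 3). The cause was not tested.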

Other observations

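All tests in this part were written down before their results were seen. The B progenitor list had log2 ratios of -1.14, 0.24 and -2.90 (CD44+ over CD44-) on the 3 pairs, a range of 3.13, while B progenitor-like cells made up 14.3%, 24.2% and 5.75% of the CD44+ libraries and 22.7%, 0% and 13.5% of the CD44- libraries. Without the B progenitor-like wells the 3 ratios were -1.62, -1.54 and -1.52, a range of 0.101. Because those wells were grouped and named by genes of the same list, leaving them out narrows the range in part by construction, and this does not test whether unequal numbers of such wells made the plates differ.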
